A study of Mus musculus with 6 samples.

How the data were processed

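The deposited data are a table of FPKM values (fragments per kilobase of gene length, scaled to the assigned fragments of the library) for 6 RNA-seq libraries of M1-polarized mouse bone marrow-derived macrophages, 3 labelled NSUN2-KO and 3 labelled NC. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a commercial RNA-seq kit. Per the submitters' processing notes, the tools named were CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, with GRCm38 (mm10) as the genome build. Their roles and settings, the annotation release and the strand setting of the counting are not given in the sources used here. The series' design text speaks of 3 biological replicates per group and in another place of a smaller number per condition, and the deposited table holds 3 columns per group. Columns were assigned to samples by group and replicate number in the sample titles, and columns of unassigned samples numbered 0.

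The FPKM values were deposited with the gene length in bases that the authors used, another column of the same table. FPKM times gene length came out as whole multiples of a fixed step within each library for 100% of values above 0 (tolerance 0.01 reads), so whole reads could be recovered. The recovered totals were 35019033 to 45636131 reads per library, and the listed genes accounted for 98.9% to 99.8% of the total implied by the step. Intervals and floors drawn from these reads cover counting error only, since reads without molecular identifiers are not independent molecules. A value of 0 was set against a floor of 3 reads per library. Gene positions are those of the deposited table, in GRCm38.

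Libraries were compared in pairs by a chi-square of their reads over genes with at least 50 reads in the pair. The mean per gene was 5.66 to 11.6 within groups and 19.3 to 30.3 between groups, where sampling alone gives 1, so that no libraries were duplicates of each other. The leading principal component carried 39.1% of the variance and separated the groups.

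Genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 (R 4.3.3) on log2(FPKM + 1), with a mean-variance trend in the empirical Bayes step and no covariate. P-values were adjusted by Benjamini-Hochberg, and an adjusted p below 0.05 was taken as a change. Log2 fold changes are on the log2(FPKM + 1) scale, NSUN2-KO minus NC. For Nsun2 an exact two-sided permutation test of the 6 FPKM values was added. For gene groups, 47 lists were fixed before the data were examined, covering inflammatory and interferon responses, antigen presentation, metabolism, translation, RNA modification, stress, the cell cycle, macrophage genes, and markers of other cells, sex and strain. The 37 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it, and adjusted over the lists. Camera compares a list with the other genes, whereas fry, also run, tests it against no change. Fisher's exact test compared genes within 10 Mb of Nsun2 with all other tested genes. Genes named in the text followed a rule fixed before the data were examined: Nsun2; the 12 protein-coding genes with the largest positive and the 12 with the largest negative log2 fold change among changed genes whose groups did not overlap; up to 4 tested members of each list by smallest unadjusted p; and Lyz2, Nos2, Tnf, Il1b, Il6, Il12b, Cxcl10, Arg1, Mrc1 and sex-linked genes. Genes outside the rule are said to be chosen after their values were seen, or are all the members of a small count or of a stated test.

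The test was checked on simulated reads with the depths of these libraries. Every gene was given the same dispersion, the median of the spread within groups. Genes with a larger spread were not simulated, so the rates below hold for that more uniform setting only. With 49 or 50 changed genes of each size among 9449 tested, limma on log2(FPKM + 1) recovered 56% of the 1.25-fold, 92% of the 1.5-fold, 98% of the 2-fold and 96% of the 3-fold changes, and 7.1% of its calls were false. Estimated log2 fold changes were 0.80 to 0.88 of the simulated ones, which is the shrinkage by the added 1 FPKM. In a simulation of lists, 1 of 1 shifted and 0 of 40 unshifted lists were called by each method. Its genes were drawn independently of each other, so it does not test the preset correlation for lists whose genes vary together.

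Alternatives fixed beforehand were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 FPKM, no trend, rescaling by median ratios or to TPM, limma voom on recovered reads, the replicate number as a block, protein-coding genes only, windows of 5 and 20 Mb, and leaving out each library. Leaving out genes on X and Y, and removing each library's trend over GC content and gene length (loess, span 0.5, GC content from the GENCODE vM21 transcripts), were added after seeing the data. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.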

Results

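RNA-seq was carried out on mouse bone marrow-derived macrophages, which are macrophages grown in culture from marrow progenitors, labelled NSUN2-KO or NC. NSUN2 is a methyltransferase that places 5-methylcytosine on tRNAs and other RNAs. The labels do not say what NC stands for or how the knockout was made. All cells had been exposed to LPS and IFN-γ, the stimuli used to bring macrophages to the inflammatory M1 state, and no unstimulated samples were analysed here. Each group had 3 libraries, given as biological replicates with no record of which animal each came from. The deposited FPKM values covered 54532 genes and corresponded to 38516800, 45636131 and 39012241 reads in NC replicates 1, 2 and 3. The NSUN2-KO replicates 1, 2 and 3 had 40105614, 35019033 and 37161700 reads. At these depths 1 read in a gene of 1 kb was worth 0.0218 to 0.0285 FPKM. The design implies 1 comparison, NSUN2-KO against NC after M1 polarization, which asks how loss of NSUN2 altered the M1 transcriptome.

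Nsun2 mRNA was lower in NSUN2-KO but not absent. Nsun2 (ENSMUSG00000021595, GRCm38 chromosome 13, positions 69533746 to 69635780, plus strand) measured 1.92 ± 0.11 FPKM in NC and 1.06 ± 0.26 FPKM in NSUN2-KO (SD, n = 3 libraries each). The knockout libraries held 55.4% of the NC level. The values were 1.88, 2.04 and 1.84 FPKM in NC replicates 1 to 3 and 0.967, 1.36 and 0.863 FPKM in NSUN2-KO replicates 1 to 3. They rested on 413 to 535 reads per NC library and 186 to 273 reads per NSUN2-KO library. On the log2(FPKM + 1) scale Nsun2 fell by 0.51 (SE 0.10, limma adjusted p = 0.0229). An exact two-sided permutation test of the 6 FPKM values gave p = 0.1, the smallest that 3 against 3 samples allow. The log2 fold change was -0.82 with a pseudocount of 0.1, -0.19 with a pseudocount of 5 and -0.89 with limma voom, each at an adjusted p below 0.05. Of the 6 fits without 1 library, 1 kept the adjusted p below 0.05 (0.0120 without NSUN2-KO replicate 2). It was 0.0534 without NC replicate 1, 0.0845 without NC replicate 2, 0.0695 without NC replicate 3, 0.0807 without NSUN2-KO replicate 1 and 0.0536 without NSUN2-KO replicate 3, and 0.113 with no filter on low values. A gene-level value does not show which exons the remaining reads came from. Srd5a1 lies within the Nsun2 locus (69573449 to 69611442), so reads of the overlapping part are uncertain where counting did not use strand, which is not given in the sources used here.

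Sex-linked genes separated the groups in all 6 libraries. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d measured 6.57 ± 0.43, 5.51 ± 0.17, 1.53 ± 0.053 and 0.561 ± 0.045 FPKM in NC (SD, n = 3) and had 0 reads in each NSUN2-KO library. Against a floor of 3 reads per library they were at least 425-fold, 285-fold, 186-fold and 106-fold lower in NSUN2-KO. Xist, the X-linked RNA that coats the inactive X chromosome of female cells, was present in every library and rose from 14.5 ± 0.88 FPKM in NC to 30.6 ± 1.20 FPKM in NSUN2-KO (log2 fold change 1.03, SE 0.05, limma adjusted p = 9.45e-05). Each NC library thus held both Xist, at 45.6% to 50.7% of the NSUN2-KO mean, and reads of all 4 Y-linked genes. This difference accompanies each gene group described here. Fold changes also followed base composition: across the tested genes, which are not independent replicates, the log2 fold change had a Spearman correlation of -0.385 with the GC content of the transcripts.

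**Figure D1:**
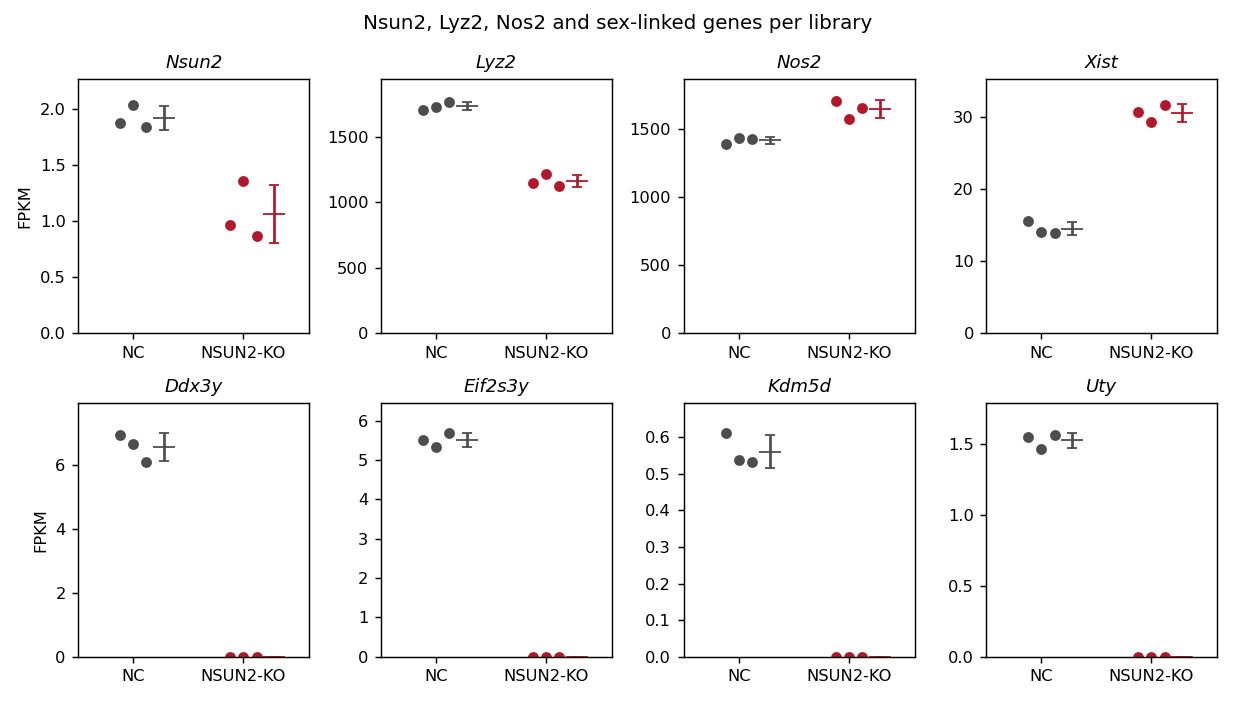
FPKM (vertical axes, linear, from 0) of Nsun2, Lyz2, Nos2, Xist and 4 Y-linked genes in NC and NSUN2-KO; points are libraries (3 per group), and the horizontal mark with bars is the mean with its SD. Nsun2 was at 0.863 FPKM or more in all NSUN2-KO libraries, while the 4 Y-linked genes were at 0 there and Xist lay between 29.4 and 31.8 FPKM against 14 to 15.5 FPKM in NC.

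Apart from genes annotated on the Y chromosome, Il6 had the largest increase and Pltp the largest decrease on the log2(FPKM + 1) scale. This ranking covers changed protein-coding genes whose groups did not overlap. Il6, a pyrogenic cytokine, rose from 4.37 ± 0.33 to 9.34 ± 1.27 FPKM (log2 fold change 0.94, SE 0.09, adjusted p = 0.00146). Il12b, the p40 subunit of IL-12 and IL-23, rose from 5.28 ± 0.25 to 9.37 ± 0.61 FPKM (log2 fold change 0.72). Ero1l, an oxidase of the endoplasmic reticulum, rose from 58.3 ± 2.28 to 100.5 ± 2.85 FPKM (log2 fold change 0.78, SE 0.04, adjusted p = 9.45e-05). Pltp, the phospholipid transfer protein, fell from 16.5 ± 0.61 to 8.31 ± 0.58 FPKM (log2 fold change -0.91, SE 0.06, adjusted p = 0.000253). Timp1, an X-linked inhibitor of matrix metalloproteinases, fell from 47.5 ± 3.95 to 25.5 ± 2.02 FPKM (log2 fold change -0.87). The other protein-coding genes among the 12 with the largest increases were Gm21860, Cxcl1, Ubd, Adm, Ak4, Il1b, Id3, Mthfd1l and Ccl3. Mthfd1l lost its call with no filter on low values (limma adjusted p = 0.0519). The other protein-coding genes among the 12 with the largest decreases were Ddx3y, Eif2s3y, Cd5l, Scimp, Tgfbi, Ccl24, Ifi27l2a, Ltb4r1, Apoe and Nupr1.

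In total 802 of 9443 tested genes differed in limma at an adjusted p below 0.05, 396 higher and 406 lower in NSUN2-KO, and 2409 had an unadjusted p below 0.05. The changes were small, with a median absolute log2 fold change of 0.27, and 93.1% of the changed genes lay below 1.5-fold. Only 5 genes reached 2-fold on the log2(FPKM + 1) scale, which understates the change of low genes: Xist, Gm42031 and Gm21860 were higher, and Ddx3y and Eif2s3y were lower. Gm42031, a long intergenic non-coding RNA on chromosome 8 that was singled out after its values were seen, measured 0.00909 ± 0.00787 FPKM in NC and 3.44 ± 0.46 FPKM in NSUN2-KO. Gm21860 is annotated near the end of the Y chromosome (positions 90754513 to 90754821) and was higher in the group with 0 reads of Ddx3y, Eif2s3y, Uty and Kdm5d. So was the overlapping pseudogene Mid1-ps1, named after its values were seen (0.724 ± 0.066 to 2.04 ± 0.66 FPKM, adjusted p = 0.0197), and where the reads of this pair came from was not tested. In all 802 changed genes the 3 values of a group lay apart from those of the other group, as they did in 31.1% of all tested genes, where chance gives 10%. The number of changed genes was 333 without NC replicate 2, 287 without NC replicate 3, 276 without NSUN2-KO replicate 1 and 457 without NSUN2-KO replicate 2. It was 265 with no filter on low values, 526 without the mean-variance trend and 1372 with limma voom on reads recovered from the FPKM values.

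**Figure D2:**
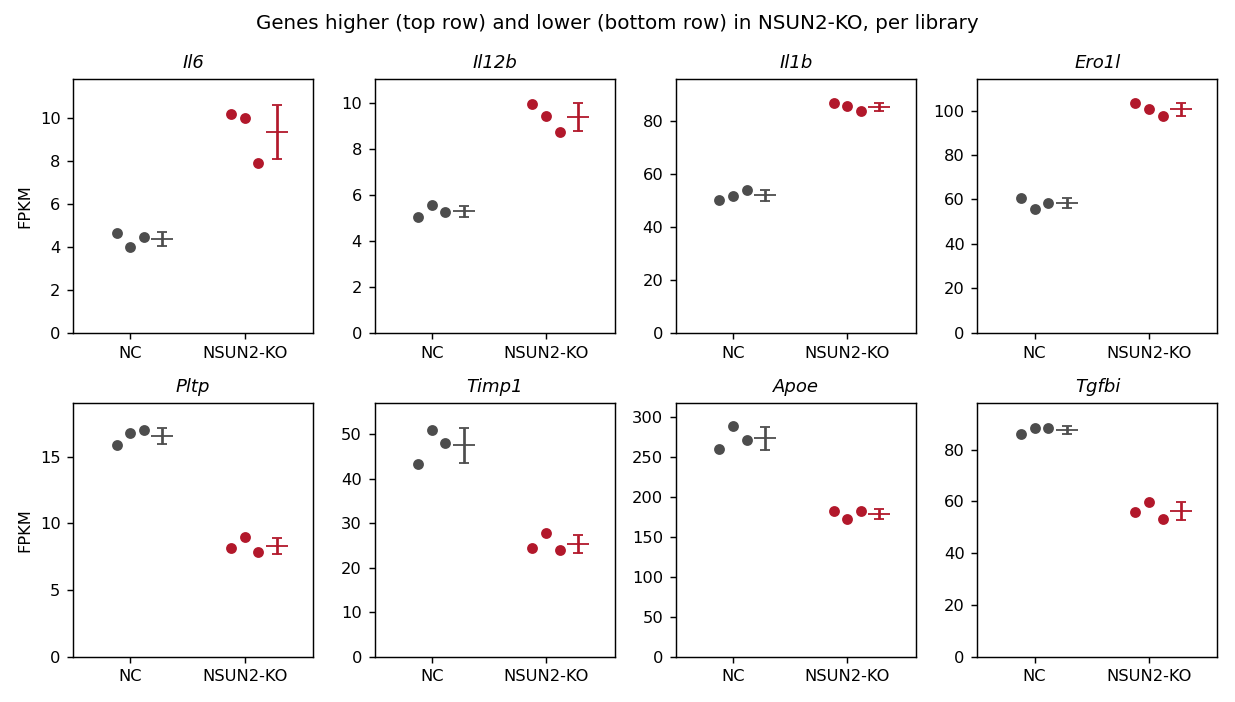
FPKM (vertical axes, linear, from 0) per library of 4 genes higher in NSUN2-KO (Il6, Il12b, Il1b, Ero1l) and 4 lower (Pltp, Timp1, Apoe, Tgfbi); points are libraries (3 per group), and the horizontal mark with bars is the mean with its SD. In each panel the 3 NSUN2-KO libraries lie wholly above or wholly below the 3 NC libraries.

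Hypoxia-responsive genes rose together. The list held hypoxia genes and targets of HIF-1, the transcription factor stabilized at low oxygen. Of its 19 tested members, 15 rose and 0 fell at an adjusted p below 0.05 over all genes tested (17 rose and 1 fell when adjusted over the list alone). Egln1 and Egln3, which encode the oxygen-sensing prolyl hydroxylases, rose from 16 ± 0.38 to 24.1 ± 0.86 FPKM and from 6.95 ± 0.50 to 11.6 ± 0.46 FPKM. Slc2a1, the glucose transporter GLUT1, rose from 69.3 ± 1.32 to 94.0 ± 2.93 FPKM. The median log2 fold change of the list was 0.35 (limma camera adjusted p = 8.03e-14, and adjusted p = 0.0367 with an estimated correlation). Of 12 lists called by camera with the preset correlation, this was the only one also called with an estimated correlation. Glycolysis genes, of which Slc2a1 and Pdk1 are also in the hypoxia list, were higher in 12 and lower in 0 of 21 tested members (14 higher and 2 lower when adjusted over the list alone). Hk2, which encodes hexokinase 2, rose from 11.3 ± 0.23 to 17.0 ± 0.71 FPKM. Pdk1, an inhibitory kinase of pyruvate dehydrogenase, rose from 5.28 ± 0.32 to 7.49 ± 0.37 FPKM and Pgam1, phosphoglycerate mutase, from 255.2 ± 5.52 to 294.3 ± 4.41 FPKM. The glycolysis list had a median log2 fold change of 0.15 (camera adjusted p = 8.41e-07, but adjusted p = 0.309 with an estimated correlation). The count of higher glycolysis genes was 5 without NC replicate 3 or NSUN2-KO replicate 1, 5 with no filter on low values and 7 without the mean-variance trend. Limma voom gave 1 lower glycolysis gene, and removing each library's trend over GC content and gene length, chosen after seeing the data, gave 1 lower hypoxia gene.

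M1 inflammatory mediators were higher in 16 and lower in 0 of 26 tested members (18 higher and 3 lower when adjusted over the list alone). Il1b rose from 51.8 ± 2.05 to 85.2 ± 1.62 FPKM (log2 fold change 0.71, SE 0.04, limma adjusted p = 0.000114). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose from 241.4 ± 10.5 to 358.8 ± 16.9 FPKM, and Slc7a2, an arginine transporter, from 56.4 ± 2.12 to 86.9 ± 5.13 FPKM. Tnf rose from 56.1 ± 1.17 to 69.6 ± 2.83 FPKM and Nos2, the inducible nitric oxide synthase, from 1415 ± 25.8 to 1644 ± 67.6 FPKM. The list had a median log2 fold change of 0.22 (camera adjusted p = 4.21e-08, but adjusted p = 0.286 with an estimated correlation). The count of higher mediators was 10 without NSUN2-KO replicate 1 and 8 with no filter on low values. Lower mediators numbered 1 without NC replicate 1, without the mean-variance trend or among protein-coding genes only, and 2 with limma voom or the GC content and gene length trend removed. Nos2 lost its call without NC replicate 3 (adjusted p = 0.0588), without NSUN2-KO replicate 1 (adjusted p = 0.0667) and with no filter (adjusted p = 0.134). Of 17 tested chemokines, 9 were higher and 1 was lower (10 higher and 3 lower when adjusted over the list alone). Ccl3 rose from 67.7 ± 0.63 to 109.8 ± 12 FPKM and Cxcl1 from 0.775 ± 0.18 to 2.25 ± 0.32 FPKM. Ccl4 rose from 103.6 ± 6.37 to 141.2 ± 13.6 FPKM and Cxcl10 from 975.9 ± 11.3 to 1171 ± 42.8 FPKM, whereas Ccl24, an eosinophil attractant, fell from 2.07 ± 0.48 to 0.979 ± 0.19 FPKM. The camera adjusted p of the chemokine list was 0.000493, but adjusted p = 0.459 with an estimated correlation. The count of higher chemokines was 5 without NC replicate 1 or NSUN2-KO replicate 2, 3 without NC replicate 2 or NSUN2-KO replicate 1, and 2 with no filter. Lower chemokines numbered 3 with limma voom and 2 among protein-coding genes only or with the GC content and gene length trend removed. Ccl24 lost its call with no filter (adjusted p = 0.138) and in the 5 fits without NC replicate 1, NC replicate 3 or any NSUN2-KO replicate (adjusted p from 0.0595 to 0.0975), and Cxcl10 with no filter (adjusted p = 0.0587). Among 19 IFN-γ-induced GTPases, which act against intracellular pathogens, 4 rose and 0 fell (7 higher and 0 lower when adjusted over the list alone). Iigp1 rose from 805.2 ± 35.3 to 958.3 ± 14.8 FPKM and Gbp4 from 414.1 ± 8.36 to 459.8 ± 10.7 FPKM (camera adjusted p of the list = 0.00443, but adjusted p = 0.459 with an estimated correlation). The count of higher GTPases was 1 without NC replicate 2, NC replicate 3, NSUN2-KO replicate 1 or NSUN2-KO replicate 2, and 2 without NSUN2-KO replicate 3. It was 0 with no filter, 1 without the mean-variance trend and 8 with limma voom. The call of the GTPase list ended when each library's trend over GC content and gene length was removed (adjusted p = 0.0937), an alternative chosen after seeing the data.

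Many genes of macrophage identity and of the lysosome moved the other way. Of 28 tested identity genes 15 fell and 1 rose (20 lower and 2 higher when adjusted over the list alone). Lyz2, the myeloid lysozyme, fell from 1736 ± 31.2 to 1163 ± 47.1 FPKM (log2 fold change -0.58, SE 0.04, limma adjusted p = 0.000282). Apoe, apolipoprotein E, fell from 273.5 ± 14.4 to 178.9 ± 5.96 FPKM, and Cd63, a tetraspanin of late endosomes, from 34.2 ± 1.20 to 26.9 ± 0.92 FPKM. Cd14, the LPS co-receptor, was the member that rose, from 205.5 ± 3.32 to 251.2 ± 1.87 FPKM. A positive fold change was seen in 6 of the 28, among them Csf1r (log2 fold change 0.02), Itgam (0.03) and Adgre1 (0.10). Csf1r, Itgam and Adgre1 were not called, and were named after their values were seen. The median log2 fold change of the list was -0.20 (camera adjusted p = 2.99e-07, but adjusted p = 0.190 with an estimated correlation). The count of lower identity genes was 9 without NC replicate 2, 8 without NC replicate 3, 7 without NSUN2-KO replicate 1 and 6 with no filter on low values, and limma voom gave 2 higher. Lysosome and phagocytosis genes fell in 10 and rose in 0 of 28 tested members (15 lower and 0 higher when adjusted over the list alone). The proteases Lgmn, Ctsb, Ctsl and Ctsd fell from 595.1 ± 17.9 to 426.5 ± 16, from 1633 ± 12.3 to 1376 ± 27.1, from 347.7 ± 7.39 to 276.6 ± 13.1 and from 868.4 ± 10.2 to 718.3 ± 36.3 FPKM. The camera adjusted p of the lysosome list was 5.75e-07, but adjusted p = 0.0751 with an estimated correlation. The count of lower lysosome genes was 5 without NC replicate 2, 6 without NC replicate 3 or NSUN2-KO replicate 1, 6 without the mean-variance trend and 4 with no filter.

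Cholesterol efflux genes and targets of the sterol receptor LXR were lower in 4 and higher in 0 of 16 tested members (5 lower and 0 higher when adjusted over the list alone). Besides Apoe, which is also an identity gene here, the sterol transporters Abcg1 and Abca1 fell from 46.0 ± 0.90 to 32.3 ± 0.068 FPKM and from 35.3 ± 0.98 to 28.3 ± 0.66 FPKM. Fabp5, a fatty acid binding protein, fell from 47.4 ± 3.04 to 31.1 ± 0.62 FPKM. The camera adjusted p of this list was 0.00149, but adjusted p = 0.190 with an estimated correlation, and limma voom gave 1 higher member. Markers of the alternative M2 state went both ways, with 5 of 17 lower and 3 higher (6 lower and 3 higher when adjusted over the list alone). The M2 list had a camera adjusted p of 0.230 and a fry adjusted p of 0.0189. The mannose receptor Mrc1 fell from 3.44 ± 0.17 to 1.94 ± 0.23 FPKM, Il4ra, a subunit of the IL-4 receptor, from 167.5 ± 4.07 to 120.6 ± 3.78 FPKM and Folr2, a folate receptor, from 14.4 ± 0.24 to 9.87 ± 0.27 FPKM. Arg1, the arginase associated with the M2 state, rose from 394.3 ± 6.71 to 443.1 ± 12.2 FPKM. The M2 count was 0 higher without NC replicate 2 or NSUN2-KO replicate 1, and 1 higher and 3 lower with no filter on low values. Arg1 lost its call without NC replicate 2 (adjusted p = 0.0664), NC replicate 3 (adjusted p = 0.0695) or NSUN2-KO replicate 1 (adjusted p = 0.0783), with no filter (adjusted p = 0.0882) and without the mean-variance trend (adjusted p = 0.0685).

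**Figure D3:**
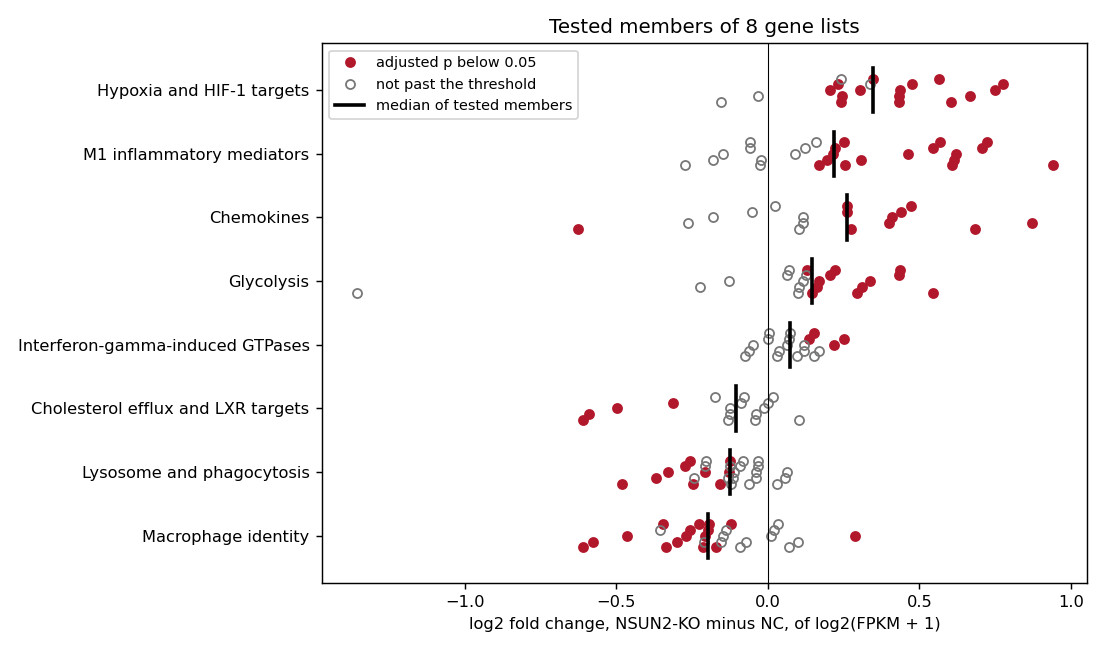
Log2 fold change (horizontal axis, NSUN2-KO minus NC, of log2(FPKM + 1)) of each tested member of 8 gene lists; filled points passed an adjusted p of 0.05 in limma, open points did not, and vertical bars are list medians. The medians range from 0.35 for the hypoxia list to -0.20 for macrophage identity, and members of the same list spread on both sides of 0; the open point at -1.36 is Gapdh, named after its values were seen.

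Beside these groups, neutrophil markers mostly fell and dendritic cell markers went both ways. The neutrophil list had a median log2 fold change of -0.20, with 1 of 6 tested members positive (camera adjusted p = 0.0653, fry adjusted p = 0.00176). Of 6 tested neutrophil markers, Csf3r, Mmp8 and S100a9 fell and Lcn2, which macrophages also express after LPS, rose from 77.2 ± 4.22 to 92.2 ± 4.05 FPKM (3 lower and 1 higher when adjusted over the list alone). S100a9 measured 28.9 ± 2.33 FPKM in NC and 22.4 ± 2.28 FPKM in NSUN2-KO. None of 17 T and NK cell markers or 13 B cell markers had a mean of at least 1 FPKM. Of 5 tested dendritic cell markers Ccr7, a chemokine receptor, rose from 2.98 ± 0.65 to 5.24 ± 0.32 FPKM (2 higher and 2 lower when adjusted over the list alone). Neutrophil markers were higher in 0 without NC replicate 3, NSUN2-KO replicate 1 or NSUN2-KO replicate 2 and without the mean-variance trend, and higher in 0 and lower in 1 with no filter. Dendritic cell markers were higher in 0 without NSUN2-KO replicate 1, with no filter or with a mean of at least 5 FPKM, and in 2 with limma voom or among protein-coding genes only. They were lower in 1 without NC replicate 1, with a mean of at least 5 FPKM or among protein-coding genes only, and in 2 with limma voom.

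Few genes of RNA modification and translation passed the test. Among 12 tested genes of the RNA cytosine-5 methylation machinery, in which Nsun2 itself was not counted, 0 passed an adjusted p of 0.05 in limma, 2 had an unadjusted p below 0.05 and 2 were higher with limma voom. Among 19 aminoacyl-tRNA synthetases 0 passed, 3 had an unadjusted p below 0.05 and 0 passed with limma voom. Of 18 tested genes of the m6A machinery Alkbh5, an RNA demethylase, rose from 34.1 ± 0.90 to 38.4 ± 1.74 FPKM (2 higher when adjusted over the list alone). The m6A count was 0 in each of the 6 fits without 1 library, with no filter, without the mean-variance trend and after rescaling to TPM. It was 3 with limma voom and 2 with a pseudocount of 5, a mean of at least 5 FPKM, median ratio scaling, protein-coding genes only or the GC content and gene length trend removed. Cytosolic ribosomal protein genes were called as a list (median log2 fold change 0.05, camera adjusted p = 0.0232, but adjusted p = 0.555 with an estimated correlation), with 2 of 50 higher, 1 lower and 0 when adjusted over the list alone. That call ended without NC replicate 1 (adjusted p = 0.258), NSUN2-KO replicate 1 (adjusted p = 0.0672) or NSUN2-KO replicate 2 (adjusted p = 0.123), with limma voom (adjusted p = 0.0850) and with a mean of at least 5 FPKM (adjusted p = 0.0549). Ribosomal protein genes were higher in 0 without NC replicate 1, NC replicate 3, NSUN2-KO replicate 1 or NSUN2-KO replicate 2, and in 1 without NC replicate 2. They were higher in 0 with no filter or no mean-variance trend, in 4 among protein-coding genes only and in 5 with the GC content and gene length trend removed (camera adjusted p = 0.00120). They were lower in 0 with no filter, with no mean-variance trend and in the 5 fits without NC replicate 2, NC replicate 3 or any NSUN2-KO replicate. Of the 13 mitochondrially encoded mRNAs, mt-Cytb rose from 335.4 ± 17.2 to 435.3 ± 34.4 FPKM and mt-Co2 from 18.3 ± 1.70 to 24.9 ± 3.65 FPKM (5 higher when adjusted over the list alone). The camera adjusted p of the mitochondrial list was 0.000939, but adjusted p = 0.320 with an estimated correlation. The mitochondrial count was 1 without NC replicate 1, 2 or 3 or NSUN2-KO replicate 2, 0 without NSUN2-KO replicate 1 and 5 without NSUN2-KO replicate 3. It was 0 with no filter, 1 without the mean-variance trend or with the GC content and gene length trend removed, 4 with a mean of at least 5 FPKM or protein-coding genes only, and 5 with limma voom.

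No excess of changed genes was detected near the targeted locus. Within 10 Mb of Nsun2, 3 of 63 tested genes changed, and all 3 fell: the protease gene Ctsl, the kinase gene Cdk20 (4.22 ± 0.28 to 3.30 ± 0.16 FPKM) and the glutaredoxin gene Glrx (138.8 ± 2.00 to 125.8 ± 3.45 FPKM). The odds ratio against all other tested genes was 0.538 (95% interval 0.108 to 1.66, Fisher's exact two-sided test p = 0.369). It was 0.242 without NC replicate 1, 1.05 without NC replicate 3 and 0.245 without NSUN2-KO replicate 3. Within 5 Mb, 0 of 33 genes changed (upper bound of the odds ratio 1.27, Fisher's exact two-sided test p = 0.110). Within 20 Mb, 4 of 130 genes changed, 3.08% against 8.56% elsewhere (odds ratio 0.339, Fisher's exact two-sided test p = 0.0248). These p-values were not adjusted over the nested windows, and the test takes genes as independent, so no depletion is claimed.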

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

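The alternatives without genes on X and Y and with the GC content and gene length trend removed were chosen after seeing the data. Every one of the 802 changed genes that an alternative tested kept its sign in that alternative. Within 1.5 times of 802 lay the counts with a pseudocount of 0.1 or 5, a mean of at least 5 FPKM, median ratio scaling, TPM, protein-coding genes only, no X and Y genes, and the trend over GC content and gene length removed, from 687 to 1021 genes. With no filter on low values 265 genes changed (147 higher, 118 lower) among 24414 tested, and the adjusted p for Nsun2 rose to 0.113 at a log2 fold change of -0.51, with more genes in the adjustment. Without the mean-variance trend 526 genes changed (254 lower). With limma voom on recovered reads 1372 changed (706 higher, 666 lower), 765 of them among the 802; the cause was not tested. Leaving out 1 library gave 276 to 596 changed genes (153 to 313 higher, 123 to 283 lower) and a log2 fold change of Nsun2 from -0.61 to -0.44 with adjusted p from 0.0120 to 0.0845, with fewer samples in each fit. At 2-fold, 16 genes were called with a pseudocount of 0.1 and 2 with a pseudocount of 5, which follows from how much each shrinks low genes. Limma voom, which changes both the scale and the variance model, called 19, and the cause was not tested. The count was 1 with a mean of at least 5 FPKM, 3 among protein-coding genes and 1 without X and Y genes, where called genes are left out. Of the 12 called lists, 1 was called with an estimated correlation. The estimate lay below the preset 0.01 for the lysosome list (0.0022) and the cholesterol efflux list (-0.048). A correlation above the preset therefore did not end those calls, and what did was not tested. For the other lists that lost their call it lay above 0.01, from 0.032 for heat shock to 0.66 for chemokines. In fry, which asks another question (change against none, not against the other genes), 4 of the 12 were not called. The odds ratio near Nsun2 was 0.339 within 20 Mb (Fisher's exact p = 0.0248, not adjusted over the windows), and the cause was not tested. With the replicate number as a block, 351 genes changed (190 higher, 161 lower), 337 of them among the 802, 12 lists were called, and Nos2 (adjusted p = 0.0565), Ccl24 (adjusted p = 0.0654) and Arg1 (adjusted p = 0.0562) lost their calls. The deviations of same-numbered libraries from their group means had correlations of -0.0095, -0.030 and 0.0034, so the numbers do not pair the libraries, and not every library correlated best with its own number. Over all alternatives, fry included, 25 calls of lists were lost, 21 calls of lists were gained, and none reversed. For 31 named genes, those with the largest changes and those always named, 19 calls were lost and none reversed. Nsun2 and the further named list members are not in that count. Depth limits low genes most: 3 reads in a gene of 1 kb correspond to 0.066 to 0.086 FPKM.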

Other observations

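The tests of library swaps, of Xist with genes that escape X inactivation, of other cell types, of the sex of the cells and of a Cre allele at Lyz2 were chosen after the patterns were seen, as was the correction for GC content and gene length, and the lists described here were fixed before the data were examined. Interferon and antigen presentation genes went both ways in NSUN2-KO. Of 37 type I interferon response genes 6 rose and 3 fell (9 higher and 5 lower when adjusted over the list alone). Ifit1bl1 rose from 446.0 ± 14.6 to 547.2 ± 14.4 FPKM and Ifi44 from 74.0 ± 2.78 to 90.9 ± 3.26 FPKM. Ifi27l2a fell from 460.7 ± 10.6 to 298.5 ± 22.3 FPKM and Rsad2, the antiviral viperin, from 3349 ± 106 to 2896 ± 18 FPKM. Of 9 tested MHC class II presentation genes, H2-Eb1 (12.3 ± 0.55 to 18.4 ± 1.48 FPKM), H2-Aa (12.5 ± 0.92 to 17.9 ± 0.97 FPKM) and Cd74, the invariant chain (103.2 ± 5.44 to 134.7 ± 7.84 FPKM), rose, and Ifi30 and a further member fell (5 higher and 3 lower when adjusted over the list alone). Among 16 inflammasome genes Nlrp3 rose from 22.4 ± 0.56 to 29.1 ± 2.71 FPKM and Mefv, the pyrin gene, fell from 22.3 ± 1.04 to 15.5 ± 0.44 FPKM. Neither these lists nor the matrix enzyme list was called by camera. The fry adjusted p was 0.00223 for matrix enzymes, 0.155 for type I interferon, 0.0721 for MHC class II and 0.0591 for inflammasome genes. The count of higher type I interferon genes was 3 without NC replicate 3, 2 without NSUN2-KO replicate 1, 2 with no filter or no mean-variance trend and 10 with limma voom. That of lower ones was 1 without NSUN2-KO replicate 1 or with no filter. MHC class II genes were lower in 1 without NC replicate 2, NC replicate 3 or NSUN2-KO replicate 1, with no filter, with no mean-variance trend and among protein-coding genes only.

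Matrix, iron and redox genes also changed. Of 15 matrix-degrading enzymes and inhibitors 6 fell and 2 rose (the same numbers when adjusted over the list alone). Besides Timp1, Timp2 fell from 4.01 ± 0.060 to 2.47 ± 0.15 FPKM and Mmp19 from 14.2 ± 0.39 to 9.25 ± 0.57 FPKM. Slc7a11, the cystine transporter, rose from 14.8 ± 0.56 to 22.7 ± 0.98 FPKM, and Slc40a1, the iron exporter ferroportin, fell from 9.32 ± 0.15 to 6.42 ± 0.39 FPKM, among 16 iron handling and ferroptosis genes of which 4 rose and 4 fell (5 and 5 when adjusted over the list alone). The NRF2 antioxidant list was called with 4 of 20 higher (camera adjusted p = 0.0201, but adjusted p = 0.309 with an estimated correlation). The heat shock list was called with 2 of 13 higher, Hsp90aa1 (81.0 ± 2.32 to 103.4 ± 1.20 FPKM) and Hspa1b (camera adjusted p = 0.0129, but adjusted p = 0.305 with an estimated correlation). The NRF2 call ended without NC replicate 1 (adjusted p = 0.0865) or NSUN2-KO replicate 2 (adjusted p = 0.0529) or with a mean of at least 5 FPKM (adjusted p = 0.0709), and the heat shock call without NSUN2-KO replicate 1 (adjusted p = 0.0510). NRF2 genes were higher in 1 without NC replicate 3 or NSUN2-KO replicate 1, in 2 without NSUN2-KO replicate 2 or with no filter, and in 7 with the GC content and gene length trend removed. They were lower in 1 without NC replicate 1, with a mean of at least 5 FPKM, with limma voom, among protein-coding genes only and with the GC content and gene length trend removed. Heat shock genes were higher in 1 in each of the 6 fits without 1 library, with no filter or with no mean-variance trend, in 4 (with 1 lower) with limma voom or the GC content and gene length trend removed, and in 5 with a mean of at least 5 FPKM. Matrix enzyme genes were higher in 1 without NC replicate 2, NC replicate 3, NSUN2-KO replicate 1 or NSUN2-KO replicate 3, with no filter or with no mean-variance trend. Iron handling and ferroptosis genes were higher in 2 and lower in 1 without NC replicate 2, NC replicate 3, NSUN2-KO replicate 1 or NSUN2-KO replicate 2, lower in 2 without NSUN2-KO replicate 3 or the mean-variance trend, and higher in 2 and lower in 1 with no filter. The median, mean and test of a list differed in sign for the M2, MHC class I, dendritic cell, ferroptosis, immediate early, cholesterol biosynthesis and DNA replication lists, none of which was called.

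Ddx3y, Eif2s3y, Uty and Kdm5d were at 0 in NSUN2-KO and Xist was higher. A swap of some libraries between the groups needs a library out of place in each group, and 0 libraries carried the pattern of these 4 Y-linked genes of the other group, a count that does not test an exchange of whole groups. A candidate explanation is that each NC library held cells of both sexes, for instance from pooled mice, and that the NSUN2-KO libraries held female cells. In that case genes that escape X inactivation should be higher in NSUN2-KO, and Eif2s3x (log2 fold change 0.29), Kdm6a (0.18), Kdm5c (0.14) and Ddx3x (0.03), chosen after the sex pattern was seen, had a median of 0.16 (SE 0.07), while Xist in NC was 47.4% of the NSUN2-KO mean. That SE is taken over the 4 genes, which are not replicates, and holds no error between libraries. Only Eif2s3x of the 4 genes passed the adjusted p threshold, and the sex of the animals is not stated in the labels. Whether the libraries of a group came from separate mice or from a shared pool is not known either. With a shared pool, the SDs and p-values given here would measure spread between cultures, not between mice.

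Of the hypoxia, glycolysis and M1 inflammatory lists 15 of 19, 12 of 21 and 16 of 26 tested members rose, and of the macrophage identity and lysosome lists 15 of 28 and 10 of 28 fell, while Cd14 rose; of these 5 lists, hypoxia alone was also called with an estimated correlation. A bias of GC content or gene length as the whole cause is argued against, since 65 of the 67 changed members of these 5 lists (97.0%) stayed changed in the same direction with that trend removed, with a median absolute log2 fold change of 0.29 before and after. A gain of cells of 7 other types in the NSUN2-KO libraries is argued against too. The types were neutrophils, T and NK cells, B cells, mast cells and basophils, erythroid cells and megakaryocytes, endothelial cells, and fibroblasts. Over the markers taken as not expressed by macrophages, the largest rise was 0.291 FPKM (Kdr), and S100a9, an abundant neutrophil transcript, fell. That comparison looks only for a rise in NSUN2-KO. More of these cells in NC, where Csf3r, Mmp8 and S100a9 were higher, was not tested. Lcn2, which rose by 15.0 FPKM, was among 6 markers set aside as also expressed by macrophages, a choice made after some values were seen. The values here did not follow that choice for every marker. Thy1, set aside, measured 0.049 FPKM in NC and 0 in NSUN2-KO, whereas Ppbp, kept, measured 7.60 FPKM in NC and 7.68 FPKM in NSUN2-KO. Dendritic cells stay open, since their 5 tested markers went both ways (median log2 fold change -0.11). The sex of the cells cannot be told apart from the knockout, because the groups differ in it in all 6 libraries (the odds ratio of X-linked genes among changed genes, 1.13, leaves effects on autosomal genes open), so that an effect of NSUN2 loss on these groups stays a hypothesis.

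Nsun2 mRNA remained at 55.4% of the NC level in NSUN2-KO, and Lyz2 was lower. A candidate explanation is a Cre recombinase inserted at Lyz2, a common way to delete a gene in macrophages, with incomplete deletion. This remains open: the log2 fold change of Lyz2 was -0.58, but 1 of 27 other tested identity genes, Apoe, was as low, 14 of the 27 also fell, and the labels do not say how the knockout was made. A deletion that leaves a shortened transcript is likewise open, as gene-level values show no exons.

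The odds ratio of changed genes within 10 Mb of Nsun2 was 0.538, with an upper bound of 1.66, below the odds ratio of 2 set beforehand for an excess from flanking strain variants, and it was 1.05 without NC replicate 3. With 6 samples there are 10 splits into equal groups, too few for a share below 0.05: the real split gave 802 changed genes, 5 genes at 2-fold and 12 lists, and the highest of the other splits gave 1, 1 and 6, so that 1 of the 10 splits was as large in each case. Gapdh, singled out after its values were seen, had the largest within-group spread of all tested genes: it measured 4.11 FPKM (638 reads) in NSUN2-KO replicate 3 and 63.2 to 85.6 FPKM in the other 5 libraries. Ppia, singled out in the same way, rose from 23.2 ± 1.20 to 37.5 ± 1.30 FPKM, and both genes are known to have many processed pseudogenes. Nnt, a strain marker also named after its values were seen, measured 0.038 ± 0.024 FPKM in NC and 0.019 ± 0.0033 FPKM in NSUN2-KO, under the test's minimum of 1 FPKM in both groups.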
